A study of Homo sapiens with 6 samples.

How the data were processed

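RNA was measured in 6 libraries, all labelled as the 786-O line, 3 labelled control and 3 labelled DPP9 knockout, with groups and replicate numbers taken from the sample titles. One table of the whole series was used, holding gene counts per library and the authors' own comparison. Each gene count was deposited as a whole number with no normalization. Per the submitters' processing notes the genome build was hg38, and Bowtie2 2.2.3, HISAT2 2.1.0, TopHat2 and HTSeq 0.6.0 were used, with no role or order given. The library kit beyond standard Illumina protocols, the strand setting, the treatment of reads that map to several places, filters and the annotation release are not given in the sources used here. This matters for antisense, paralogous and pseudogene-rich genes, whose reads may be shared or lost. The table also holds the authors' fold ratio, log2 ratio and p-value columns for knockout over control, and a mean signal that matched the mean of counts divided by median-of-ratios size factors, all as deposited by the authors with the test tool not stated. All 7397 genes the table marks as significant are those with an adjusted p under 0.05 and an absolute log2 ratio of at least 1, and 9103 genes have no adjusted p there.

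The table lists 33540 genes, each with at least 1 count in some library, and 0 rows without a gene name. Of these, 33281 identifiers were found in GENCODE release 29 (hg38), and 94.84% of all genes listed had the same coordinates there. Library totals ran from 15284493 to 17400699 counts. Replicates were compared in pairs with a chi-square test over genes, and each pair differed beyond sampling noise (chi-square per degree of freedom 5.32 to 8.02 in control and 5.93 to 23.5 in knockout), so none was counted as a repeat deposit. Knockout replicate 1 differed most from its group (21.8 and 23.5).

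Counts were tested with edgeR 4.0.16 (R 4.3.3) using filterByExpr, TMM scaling and the two-sided quasi-likelihood F test, with group as the only term and all 6 libraries in the fit. Adjusted p-values are Benjamini-Hochberg over the 16415 genes kept, with a threshold of 0.05, and the common biological coefficient of variation was 0.106. CPM values are TMM-scaled, and values with ± are mean and SD over 3 libraries unless marked SE. Folds are from the fitted log2 change. For a gene with 0 counts in a group the fold is a lower bound against a floor of 3 counts over that group, and with 1 to 3 counts a ratio is given with an exact 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

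Before the data were examined, 41 gene lists (1161 genes, 1130 of them matched) were fixed for a study of NRF2 and ferroptosis in a renal carcinoma line, with markers of other tissues and lines among them. Lists with at least 5 tested genes (40) were tested with camera (limma 3.58.1, two-sided, preset correlation 0.01), camera with an estimated correlation, and fry, with Benjamini-Hochberg adjustment over the lists. The form with an estimated correlation takes its degrees of freedom from 6 libraries and has little power. A list that does not pass it is therefore not shown to be unchanged. List counts are of members past the threshold over all genes tested, and counts adjusted over the list alone were the same unless given. In 3 lists, 4 members had 0 counts in one group, and the list medians were the same with these at their bound. The rule for named genes was also fixed then. It took DPP9, DPP8 and 15 NRF2, ferroptosis and inflammasome genes, the 10 largest rises and the 10 largest falls, and up to 3 passing members with the smallest adjusted p of each list. Genes for rises and falls needed an adjusted p under 0.05, at least 5 CPM in the higher group, no overlap between groups and a symbol that is not a clone or pseudogene name. Y-linked genes and XIST are not reported, and a few other genes the rule takes are not reported here and were not replaced.

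The fitting code was checked on simulated counts for this comparison (16030 genes). It recovered 35.4% of 65 genes changed by 0.5 log2, 79.7% of 64 changed by 1 and 100% of 64 changed by 2. There were 12 false calls among 150 (8%). The single raised list was found and 0 unchanged lists were called. Few genes were changed there and genes were drawn independently, while 74.13% passed in the data. The simulation therefore checks the code and sets no detection limit for these libraries. Alternatives were DESeq2 1.42.0 size factors, library-size scaling alone, other count filters, the DESeq2 and limma-voom tests, the replicate number as a block, each library left out, protein-coding genes alone, no mitochondrial genes, a test against a 1.2-fold change and removal of GC content and length trends. Thinning of all libraries to 15284493 counts, joint removal of GC and length trends, removal of block medians and a single count of near-identical homeobox copies were added after seeing the data. Tests of position along the autosomes used 12961 protein-coding genes in 127 blocks and 1000 shuffles of gene order.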

Results

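RNA sequencing was used to compare libraries labelled as 786-O cells with DPP9 knocked out with libraries labelled as control 786-O cells. 786-O is an established line from a human clear cell renal cell carcinoma. DPP9 is a cytosolic serine dipeptidyl peptidase. The series asked how its loss changed the transcriptome, with NRF2, the transcription factor of the oxidative stress response, ferroptosis, an iron-dependent form of cell death, and resistance to the kinase inhibitor sorafenib as its stated subjects. There were 3 control and 3 DPP9 knockout libraries. Total counts were 16225994, 16300766 and 15315268 in control replicates 1, 2 and 3, and 17400699, 16682837 and 15284493 in knockout replicates 1, 2 and 3. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

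DPP9 itself (ENSG00000142002, chromosome 19, 4675224 to 4724673, minus strand, hg38) was measured at 211, 180 and 207 CPM (counts scaled to the size of each library) in the 3 control libraries and at 26.1, 26.0 and 23.7 CPM in the 3 knockout libraries. The mean was 199 ± 16.8 (SD, n = 3) in control and 25.3 ± 1.38 (SD, n = 3) in knockout, 7.88-fold lower, with a log2 fold change of -2.98 ± 0.11 (SE, edgeR adjusted p = 2.34e-11). The authors' deposited table gives a log2 ratio of -3.01 for DPP9. The value covers the whole gene, an antisense gene overlaps it, and the strand setting of the counting is not given in the sources used here. DPP8, its closest relative, was 1.73-fold lower (74.5 ± 4.57 against 43.0 ± 4.81 CPM, SD, n = 3 each). Among the 8 dipeptidyl peptidase family genes tested, 3 rose and 3 fell. DPP4, a membrane-bound member, rose 5.36-fold, CTSC, a lysosomal one, rose 4.16-fold, and DPP7 fell from 87.7 ± 16.2 to 5.39 ± 1.72 CPM (SD, n = 3 each). The median log2 fold change of the family was -0.10 and the mean 0.12, with the camera test pointing up (camera adjusted p = 0.763). NLRP1 and CARD8, inflammasome sensors that DPP9 is known to restrain, were 1.62-fold and 1.55-fold lower. Of the 16 inflammasome and pyroptosis genes tested, 7 rose and 5 fell (camera adjusted p = 0.37). TXNIP rose 5.62-fold, CASP1, the inflammatory caspase, 5.43-fold and IL1B 11.9-fold, and the median of this list, 0.19, was -0.13 with library-size scaling alone.

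**Figure D1:**
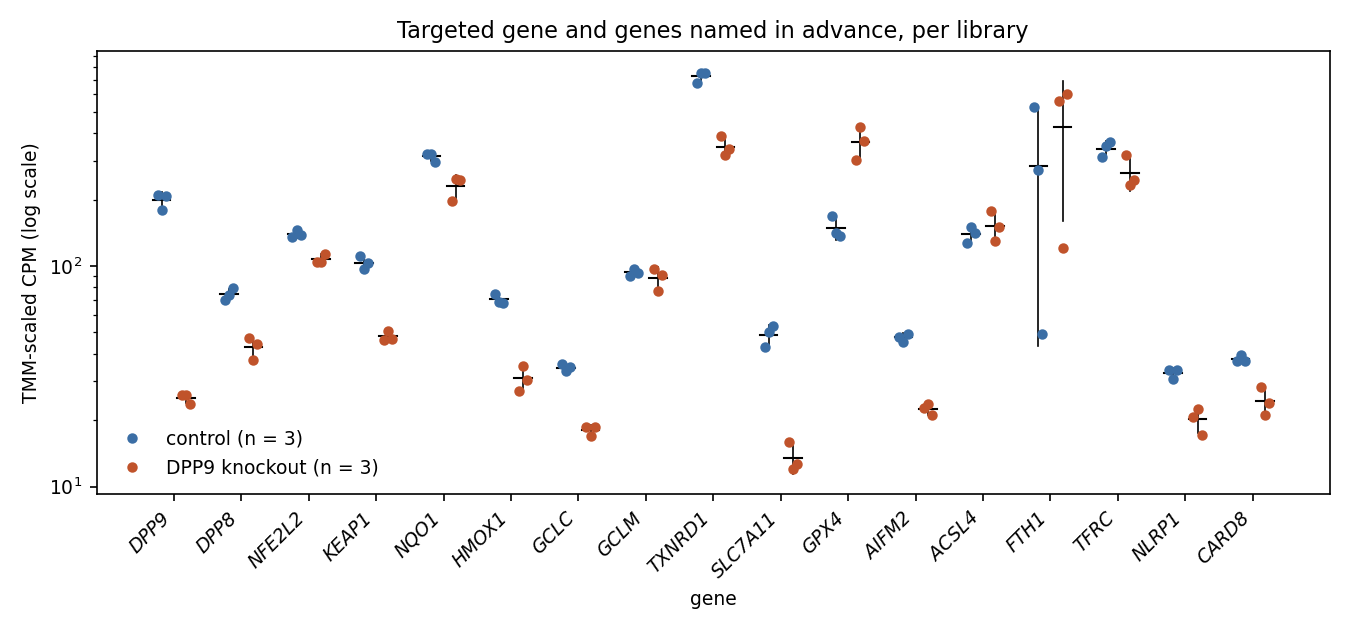
TMM-scaled CPM (log axis) of the targeted gene and 16 genes named in advance in each of the 3 control and 3 DPP9 knockout libraries. Points are libraries, horizontal bars group means and vertical bars 1 SD. DPP9 lies between 180 and 211 CPM in control and between 23.7 and 26.1 CPM in knockout, and FTH1 spans 49.4 to 528 CPM within control.

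Most expressed genes differed between the groups. Of 16415 genes tested, 12168 (74.13%) passed the edgeR test, 5930 higher and 6238 lower in knockout, and 6545 of these differed at least 2-fold, 3366 higher and 3179 lower. The 3 knockout values did not overlap the 3 control values in 12422 genes (75.67%, where chance gives 10%). The authors' deposited table marks 7397 genes as significant, 3706 up and 3691 down. Across genes, log CPM correlated at r of at least 0.988 between libraries of one group and at most 0.829 between groups. Without TMM scaling the median log2 fold change of all genes moved from -0.03 to -0.35 and the split became 4425 higher and 8102 lower, or 2546 and 4500 among genes that differed at least 2-fold. Directions are therefore given relative to the bulk of genes. The libraries behind each gene group also differed in CDKN2A, a marker of cell line identity (63.4 ± 16.1 CPM in control and 0.917 ± 0.367 CPM in knockout, SD, n = 3 each), and in fold changes that followed chromosome position. Rises and falls given here are differences between these libraries, and none can be assigned to DPP9 alone.

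Of the 10 largest rises, SLC1A6, a glutamate transporter, had 0 counts in the control libraries and was at least 101.6-fold higher in knockout, against a floor of 3 counts over the group. SLC6A12, a betaine and GABA transporter, rose from 0.321 ± 0.17 to 74.3 ± 2.27 CPM (SD, n = 3 each, log2 fold change 7.83 ± 0.20, SE, edgeR adjusted p = 1.57e-12). SMTNL2 rose 159-fold, DDIT4L 98.4-fold, RAB17 79.99-fold, UGT3A2 70.3-fold and the FGF co-receptor KLB 63.2-fold. The medium-chain acyl-CoA synthetase genes ACSM2B and ACSM2A had 1 and 2 counts over the control libraries, for ratios of 343.5 (95% counting interval 61.2 to 13610) and 227.4 (62.5 to 1884). They are near-identical neighbours, so how reads divide between them is uncertain. The 10 largest falls all had 0 counts in knockout. MAGEA4, a cancer-testis antigen gene on the X chromosome, went from 327 ± 10.5 CPM (SD, n = 3) to 0, at least 4810-fold lower. MAGEA10 was at least 966.6-fold lower, GTSF1 719.1-fold, TSPYL5 663.4-fold, SALL3 598.9-fold, BEX1 589.8-fold, TRIM58 381.7-fold and ZNF569 303.2-fold. RHOXF2 and RHOXF2B, near-identical copies whose separate values are uncertain, were at least 356.4-fold and 350.9-fold lower.

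NRF2 target genes were higher on balance in knockout, but several of the best known moved the other way. Of 43 tested, 26 rose and 11 fell (27 and 11 adjusted over the list alone), with a median log2 fold change of 0.59 (camera adjusted p = 0.0352, and adjusted p = 0.363 with an estimated correlation). The median has the value of FTH1 (0.593, edgeR adjusted p = 0.393), a gene that varied widely within groups. It was 0.28 with library-size scaling alone and 0.41 over the 41 members on the autosomal blocks. AKR1B1, aldose reductase, rose from 1532 ± 70.4 to 16625 ± 2233 CPM (SD, n = 3 each), and AKR1C1 and AKR1C3, aldo-keto reductases with close paralogs that may share reads, rose 9.84-fold and 5.72-fold. SLC7A11, the cystine transporter subunit, fell 3.60-fold, from 48.8 ± 5.36 to 13.5 ± 2.097 CPM (SD, n = 3 each). Lower levels were also measured for HMOX1, haem oxygenase (2.28-fold), TXNRD1, thioredoxin reductase (2.08-fold), GCLC, the catalytic subunit of glutathione synthesis (1.92-fold), and NQO1, a quinone reductase (1.37-fold). GCLM, the partner of GCLC, was at 93.5 ± 3.49 and 88.6 ± 10.1 CPM (SD, n = 3 each) and did not pass (edgeR adjusted p = 0.508). NFE2L2, which encodes NRF2, was 1.30-fold lower (140 ± 5.48 against 108 ± 5.48 CPM, SD, n = 3 each, edgeR adjusted p = 0.00177), a call lost in a test against a 1.2-fold change (adjusted p = 0.0575). Of 19 NRF2 pathway regulators, 3 rose and 12 fell (camera adjusted p = 0.0709). KEAP1, the adaptor that marks NRF2 for degradation, was 2.16-fold lower, SQSTM1 3.19-fold and the repressor BACH1 3.50-fold.

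Genes of ferroptosis moved both ways. Of 31 suppressors tested, 14 rose and 10 fell (median 0.36, camera adjusted p = 0.456). GPX4, the lipid hydroperoxide peroxidase, rose 2.46-fold, from 149 ± 17.4 to 367 ± 62.2 CPM (SD, n = 3 each), while AIFM2, which encodes FSP1, fell 2.11-fold. PLIN2, a lipid droplet coat gene, rose 4.98-fold and LCN2, lipocalin 2, rose 17.96-fold. Of 33 promoters tested, 12 rose and 11 fell (camera adjusted p = 0.688), and their median, 0.01, was -0.31 with library-size scaling alone. Among them DPP4 rose 5.36-fold, PTGS2 9.11-fold and FADS2 3.19-fold, while ACSL4, at 139 ± 11.7 and 152 ± 23.7 CPM (SD, n = 3 each), did not pass (edgeR adjusted p = 0.338). Glutathione metabolism had 18 of 33 genes higher and 8 lower (median 0.83, camera adjusted p = 0.0709). GGT1 rose 6.03-fold and GSTM4 5.18-fold, while ANPEP, an aminopeptidase, fell 16.1-fold. Selenoproteins and the thioredoxin system had 23 of 33 genes higher and 8 lower (median 0.72, camera adjusted p = 0.0192, and adjusted p = 0.362 with an estimated correlation). PRDX2 rose 7.74-fold and PRDX4 3.66-fold.

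Iron homeostasis genes were split, with 8 of 26 higher and 10 lower. Their median log2 fold change was 0.09 (-0.23 with library-size scaling alone), their mean -0.34, and the camera test pointed down (camera adjusted p = 0.935). CYBRD1, a ferric reductase, fell from 80.1 ± 3.23 to 0.271 ± 0.062 CPM, STEAP1 fell 4.88-fold and CP, ceruloplasmin, rose 5.95-fold. TFRC, the transferrin receptor, was 1.29-fold lower with overlapping groups (edgeR adjusted p = 0.0138), a call lost without control replicate 3 (adjusted p = 0.0532), knockout replicate 2 (0.0947) or knockout replicate 3 (0.0796). FTH1, the ferritin heavy chain, was at 283 ± 240 CPM in control and 427 ± 266 CPM in knockout (SD, n = 3 each), and its difference was smaller than the spread between replicates (edgeR adjusted p = 0.393). Without control replicate 1, FTH1 had a log2 fold change of 1.41 and an edgeR adjusted p of 0.049. Of the 6 metallothionein list genes, 1 rose and 3 fell (1 and 1 adjusted over the list alone), with a median of -0.18, a mean of 0.04 and a camera test pointing down (camera adjusted p = 0.968). MT1F rose 3.24-fold and MTF1 fell 1.56-fold. MT1X was 1.63-fold lower with overlapping groups (edgeR adjusted p = 0.0364), a call lost without control replicate 1 (0.0536), control replicate 2 (0.164), knockout replicate 1 (0.0922) or knockout replicate 2 (0.137), and metallothionein genes are similar enough that shared reads leave single members uncertain. Cholesterol biosynthesis had 10 of 24 genes higher and 4 lower (10 and 3 adjusted over the list alone, camera adjusted p = 0.22), with a median of 0.09 that was -0.23 with library-size scaling alone. SREBF2, a transcription factor of sterol synthesis, rose 2.79-fold. Fatty acid and lipid droplet metabolism had 20 of 35 higher and 7 lower (camera adjusted p = 0.0638), with SCD5, a desaturase, 23.5-fold lower.

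Hypoxia-inducible factor (HIF) targets were among the groups with the clearest rise. Of 39 tested, 30 rose and 4 fell, with a median log2 fold change of 1.33 (camera adjusted p = 2.74e-06, and adjusted p = 0.154 with an estimated correlation). EGLN3, a prolyl hydroxylase induced by HIF, rose from 45.01 ± 3.06 to 652 ± 12.4 CPM, NDRG1 from 98.4 ± 2.15 to 1202 ± 38.7 CPM and CA12, a carbonic anhydrase, from 124 ± 3.94 to 836 ± 11.02 CPM (SD, n = 3 each). Glycolysis followed with 16 of 22 genes higher and 3 lower (median 0.79, camera adjusted p = 0.0113, and adjusted p = 0.251 with an estimated correlation). These groups rose in libraries that also differed in kidney lineage genes and in CDKN2A, so the rise cannot be assigned to DPP9 loss alone. SLC2A1, the glucose transporter, rose 3.89-fold, PFKL 3.62-fold and HK1 2.55-fold. The 13 mitochondrially encoded genes all rose (median 0.80, camera adjusted p = 0.00236, and adjusted p = 0.362 with an estimated correlation), led by MT-CO1 (3.13-fold), MT-ND6 (2.80-fold) and MT-ND4 (2.26-fold). Their median lay at percentile 84.51 of 10000 random lists matched on expression, which is not unusual for such lists. Mitochondrial genes took 4.08 ± 0.227% of counts in control and 8.55 ± 0.676% in knockout, mitochondrial rRNA 0.536 ± 0.0228% and 1.88 ± 0.181%, and the 10 genes with most counts 5.43 ± 0.177% and 10.87 ± 0.589% (SD, n = 3 each). Of the 59 nuclear-encoded respiratory chain genes, 21 rose and 13 fell (20 and 13 adjusted over the list alone, camera adjusted p = 0.456), and their median of 0.16 was -0.16 with library-size scaling alone. UQCRH was 7.82-fold lower, NDUFS3 1.92-fold lower and SDHA 2.81-fold higher.

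Genes of growth and DNA synthesis were lower in knockout. None of the 33 MYC target and ribosome biogenesis genes rose and 31 fell (32 adjusted over the list alone), with a median of -1.07 (camera adjusted p = 8.15e-07, and adjusted p = 0.206 with an estimated correlation). ODC1, the first enzyme of polyamine synthesis, fell 11.04-fold, and the nucleolar genes NCL and NOP58 fell 2.97-fold and 2.76-fold. DNA replication had 38 of 46 genes lower and 3 higher (median -0.75, camera adjusted p = 2.86e-05, and adjusted p = 0.154 with an estimated correlation), with the helicase subunits MCM4 and MCM7 3.08-fold and 2.60-fold lower and UHRF1 3.42-fold lower. Mitosis had 20 of 39 lower and 4 higher (median -0.29, camera adjusted p = 0.043, and adjusted p = 0.362 with an estimated correlation), with NDC80, TTK and HMMR 3.22-fold, 2.38-fold and 2.496-fold lower. The mitosis call was lost without control replicate 2 (camera adjusted p = 0.0525), knockout replicate 1 (0.063) or knockout replicate 2 (0.0572). Among replication-dependent histones, 12 of 18 were lower and 2 higher (median -0.77, camera adjusted p = 0.0299, and adjusted p = 0.251 with an estimated correlation), a call lost without control replicate 1 (0.0752) or knockout replicate 1 (0.0849). HIST1H2BK fell 2.52-fold, HIST1H2BC fell 5.37-fold, and HIST1H3H went from 4.21 ± 0.332 CPM (SD, n = 3) to 0 counts, although reads shared between histone copies leave single genes uncertain. Targets of p53 went the other way, with 20 of 32 higher and 6 lower (median 0.51, camera adjusted p = 0.0204, and adjusted p = 0.206 with an estimated correlation). BTG2, an antiproliferative gene, rose 4.50-fold and GDF15 4.53-fold, while PMAIP1, which encodes the proapoptotic NOXA, fell 11.1-fold. Among 37 apoptosis regulators, 15 rose and 14 fell, with a median of 0.08 (-0.24 with library-size scaling alone), a mean of -0.05 and a camera test pointing up (camera adjusted p = 0.763). TNFSF10, the death ligand TRAIL, rose 25.2-fold and the survival gene MCL1 fell 3.15-fold.

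Among genes of protein synthesis and folding, the heat shock list passed the camera test and the others did not. Heat shock proteins had 15 of 21 genes lower and 3 higher (17 and 3 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 0.0116, and adjusted p = 0.362 with an estimated correlation). HSP90AA1 fell from 2912 ± 172 to 398 ± 24.9 CPM, whereas the small heat shock genes HSPB8 and CRYAB rose 5.04-fold and 5.81-fold. Of 33 proteasome subunits, 16 fell and 1 rose (camera adjusted p = 0.0549), with PSMC1, PSMB7 and PSMD1 3.26-fold, 2.43-fold and 1.68-fold lower. Cytosolic ribosomal proteins had 23 of 56 genes lower and 9 higher (21 and 8 adjusted over the list alone, camera adjusted p = 0.152). RPL26 and RPL7 were 3.77-fold and 2.13-fold lower, values made uncertain by their many pseudogenes. Integrated stress response genes had 17 of 35 lower and 8 higher (camera adjusted p = 0.128), with the tryptophanyl-tRNA synthetase gene WARS, MTHFD2 and CEBPG 9.60-fold, 4.76-fold and 4.73-fold lower. The unfolded protein response had 10 of 24 lower and 8 higher, with a median of -0.08, a mean of -0.04 and a camera test pointing up (camera adjusted p = 0.968). HSPA5 and SEL1L fell 2.07-fold and 2.32-fold and PDIA4 rose 1.90-fold. Nuclear-retained and small RNA host transcripts had 7 of 13 lower and 4 higher (8 and 4 adjusted over the list alone, camera adjusted p = 0.243), with SNHG5, SNHG1 and GAS5 8.20-fold, 2.96-fold and 2.07-fold lower. Lysosome and autophagy genes were higher in 21 of 38 and lower in 10 (22 and 11 adjusted over the list alone, camera adjusted p = 0.0666), with the cathepsin genes CTSD and CTSZ 6.98-fold and 5.84-fold higher and MITF 3.73-fold higher.

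Among immune and inflammatory genes, the interferon, antigen presentation and NF-kB lists were higher on balance in knockout. Interferon-stimulated genes rose in 29 of 41 and fell in 10 (median 1.16, camera adjusted p = 0.00195, and adjusted p = 0.177 with an estimated correlation), and the antiviral genes IFITM1, MX1 and MX2 rose 10.1-fold, 5.73-fold and 6.27-fold. Antigen presentation genes rose in 19 of 22 and fell in 1 (median 1.2, camera adjusted p = 6.39e-05, and adjusted p = 0.206 with an estimated correlation). CD74, the class II invariant chain, rose from 49.97 ± 4.75 to 324 ± 30.8 CPM, HLA-DMA rose 11.5-fold and HLA-E 3.09-fold, with reads shared between HLA genes leaving the last uncertain. NF-kB and inflammatory cytokine genes rose in 26 of 38 and fell in 10 (27 and 10 adjusted over the list alone), with a median of 0.95 (camera adjusted p = 0.00495, and adjusted p = 0.183 with an estimated correlation). CCL20, a chemokine, rose 19.6-fold, while CXCL2, another, and TRAF1 fell 13.4-fold and 10.996-fold. Only 4 immune cell marker genes were tested, too few for a list test. CD14 and KLRD1 rose to 4.35 ± 0.358 and 4.49 ± 0.813 CPM and ITGAM fell to 0.778 ± 0.406 CPM (SD, n = 3 each).

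Matrix genes rose while immediate early genes fell. Collagens and matrix genes were higher in 25 of 31 and lower in 4 (median 1.70, camera adjusted p = 1.19e-05, and adjusted p = 0.362 with an estimated correlation). SPARC rose from 221 ± 6.66 to 1352 ± 60.7 CPM, the lysyl oxidase gene LOXL2 from 309 ± 16.5 to 2128 ± 130 CPM and COL1A1 from 2.03 ± 0.373 to 28.6 ± 3.10 CPM (SD, n = 3 each). Epithelial-mesenchymal transition genes rose in 16 of 25 and fell in 7 (17 and 7 adjusted over the list alone, camera adjusted p = 0.0549). This list holds markers of both states, and the epithelial genes CDH1 and KRT19 rose 40.2-fold and 5.31-fold. Targets of TGF-beta and YAP rose in 13 of 27 and fell in 10 (camera adjusted p = 0.217), with a median of 0.29 that was -0.03 with library-size scaling alone. CTGF and LTBP2 fell 4.62-fold and 27.0-fold and BMP4 rose 7.82-fold. Immediate early and MAPK feedback genes fell in 19 of 27 and rose in 4 (median -1.11, camera adjusted p = 0.00149, and adjusted p = 0.183 with an estimated correlation). FOSL1, an AP-1 subunit, fell from 554 ± 51.7 to 19.1 ± 1.07 CPM, SPRY4, a feedback inhibitor of MAPK signalling, from 76.4 ± 2.15 to 1.48 ± 0.097 CPM, and PHLDA1 fell 7.001-fold. The sorafenib target kinases and drug transporters rose in 13 of 20 and fell in 4 (14 and 4 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 0.0484, and adjusted p = 0.381 with an estimated correlation). That call was lost without control replicate 3 (camera adjusted p = 0.0675), knockout replicate 1 (0.082) or knockout replicate 2 (0.0802). FGFR2 rose 15.8-fold, the drug efflux pump gene ABCB1 4.88-fold and SLCO1B3 8.61-fold.

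**Figure D2:**
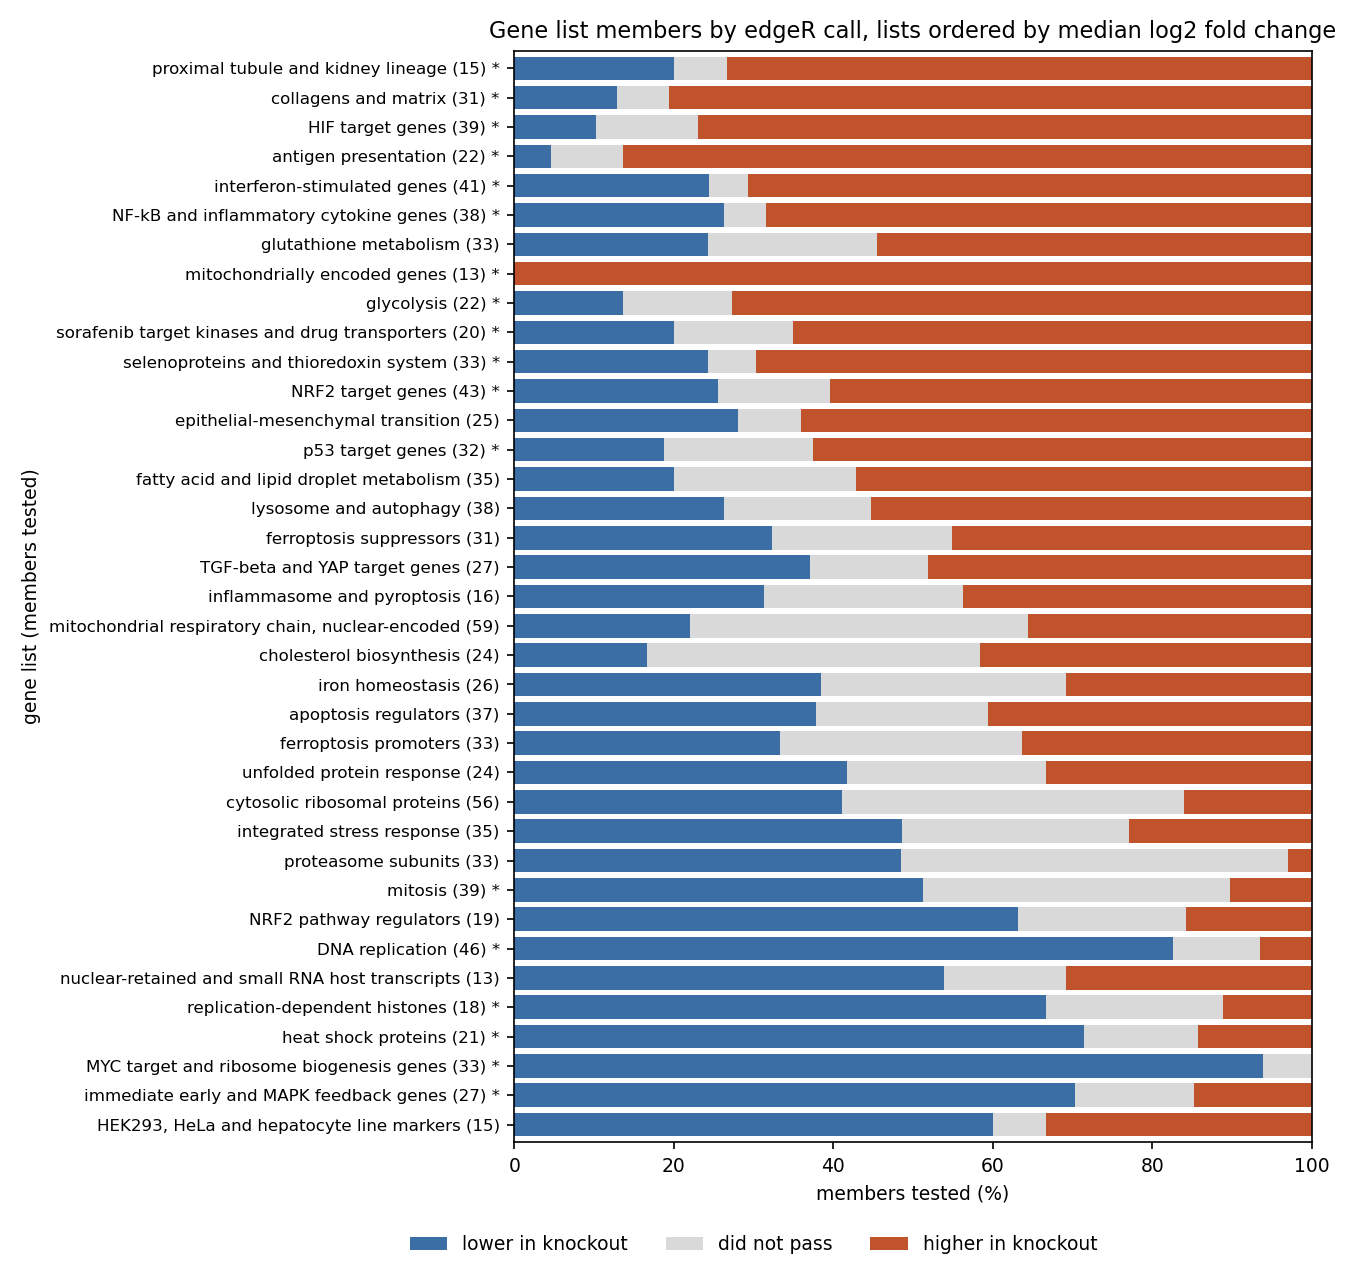
Share of tested members (%) of each gene list with at least 10 tested members that were higher (orange), lower (blue) or did not pass the edgeR test (grey) in 3 DPP9 knockout against 3 control libraries. Numbers in brackets are members tested and asterisks mark camera adjusted p under 0.05 with the preset correlation. None of the lists kept that call with an estimated correlation, a test of little power with 6 libraries.

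Markers of tissue and of other cell lines also separated the groups. Proximal tubule and kidney lineage genes rose in 11 of 15 and fell in 3 (median 2.03, camera adjusted p = 0.0145, and adjusted p = 0.251 with an estimated correlation). PAX8, a kidney lineage transcription factor, rose from 89.5 ± 5.66 to 677 ± 36.4 CPM, and the kidney cadherin gene CDH16 from 4.05 ± 1.17 to 58.9 ± 3.71 CPM (SD, n = 3 each). Endothelial and fibroblast markers rose in 6 of 8 and fell in 2 (camera adjusted p = 0.082), with RGS5 and ACTA2 reaching 19.8 ± 3.23 and 18.2 ± 1.11 CPM in knockout. Of 15 markers of HEK293, HeLa and hepatocyte lines, 5 rose and 9 fell (5 and 10 adjusted over the list alone, camera adjusted p = 0.22). LIN28B fell from 43.7 ± 2.65 to 0.783 ± 0.230 CPM and CDKN2A, a cell cycle inhibitor gene, from 63.4 ± 16.1 to 0.917 ± 0.367 CPM (SD, n = 3 each). CDKN2B, its neighbour, had 1037 counts over the control libraries and 1 over the knockout libraries, a ratio of 857.4 (95% counting interval 153.6 to 33900).

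Fold changes also followed chromosome position. In consecutive blocks of about 100 tested protein-coding genes on the autosomes, block medians ran from -1.04 to 0.86 (log2), and whole-chromosome medians from -0.41 on chromosome 14 to 0.43 on chromosome 22. On chromosome 9 (hg38), MTAP (21802543 to 21937651), CDKN2A (21967753 to 21995301), CDKN2B (22002903 to 22009363) and DMRTA1 (22446841 to 22455740) were at 50.9, 63.4, 19.4 and 6.73 CPM in control and at 0.137, 0.917, 0.021 and 0.025 CPM in knockout. KLHL9, before them (21329671 to 21335380), was at 31.3 ± 1.88 and 26.8 ± 3.34 CPM (SD, n = 3 each) and did not pass. IFNE, a low gene between KLHL9 and MTAP, fell from 2.54 ± 0.308 to 0.65 ± 0.261 CPM, and ELAVL2, after DMRTA1, from 1.76 ± 0.365 to 0.964 ± 0.257 CPM (SD, n = 3 each, edgeR adjusted p = 7.26e-05 and 0.0234). The neighbours of CDKN2A were chosen after their values were seen.

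**Figure D3:**
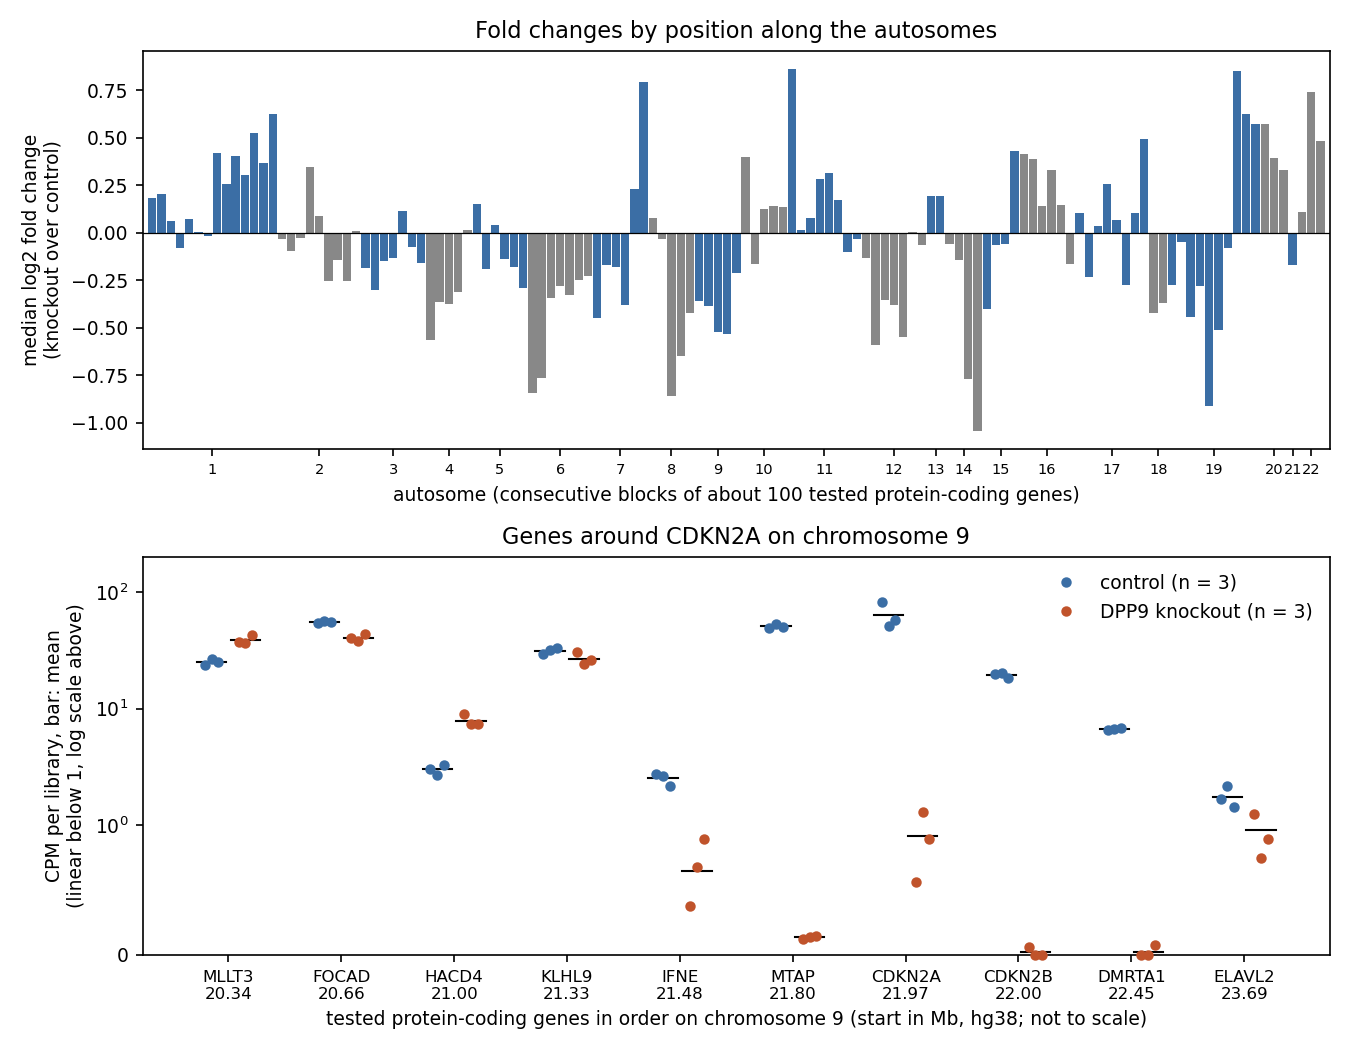
Above, median log2 fold change (knockout over control) of each of 127 consecutive blocks of tested protein-coding genes, in order along the autosomes, with alternate chromosomes in blue and grey. Below, CPM per library (points, linear below 1 and log above, bars at means) of 10 tested genes around CDKN2A on chromosome 9, where MTAP, CDKN2A, CDKN2B and DMRTA1 lie between 6.73 and 63.4 CPM on average in control and below 1 CPM in knockout.

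The authors' deposited table has the same signs for the NRF2 and ferroptosis genes copied from it. Its log2 ratios are -0.48 for NQO1, -0.97 for GCLC, -0.11 for GCLM, -1.88 for SLC7A11 and 1.27 for GPX4. Of the 40 lists tested, 18 passed the camera test with the preset correlation of 0.01 and 0 passed with an estimated correlation. The second form has little power with 6 libraries, so these losses do not by themselves show correlation between members. As a test of each list by itself, fry gave 36 lists that moved on balance one way, a test that does not compare a list with other genes.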

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

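Thinning, joint removal of GC and length trends, removal of block medians and the single count of near-identical homeobox copies were chosen after the result was seen, and the other alternatives before the data were examined. The count of changed genes was 12168 and ran from 10274 (protein-coding genes alone) to 13967 (no count filter), and that of genes changed at least 2-fold, 6545, ran from 5106 to 8483, within 1.5 times in each alternative. Leaving out 1 library at a time gave 11667 to 12681 and 6696 to 6939 genes. Library-size scaling alone moved the share of higher genes from 48.73% to 35.32%. DPP9 kept its direction and passed in all alternatives run.

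The gene lists past the threshold went from 18 to 0 with an estimated correlation and to 36 with fry. Some that lost the call had an estimated correlation below the preset 0.01. In DNA replication it was -0.001536, and camera p went from 2.862e-06 to 0.004879. It was also below the preset in p53 targets (-0.0003655), interferon-stimulated genes (-0.002437) and NF-kB genes (-0.002653). Correlation between members therefore does not account for these losses. For them the test differed in its degrees of freedom, taken from 6 libraries and not from the number of genes. The cause of the change with fry was not tested. NRF2 target genes, with a median of 0.5928, then had an adjusted p of 0.3625 with an estimated correlation, while ferroptosis suppressors (0.3634, adjusted p = 0.001095) and promoters (0.007465, adjusted p = 0.002116) passed with fry, which does not compare a list with other genes. Metallothioneins (-0.1792) pointed up with fry (adjusted p = 0.002284), and the cause was not tested. Of 760 values of single lists under the alternatives, 673 kept direction and side of the threshold, 32 lost the call, 53 gained it, 1 reversed and 1 without a test moved. Of these, 18 losses came with an estimated correlation and 17 gains with fry, and the rest with other alternatives. The value that moved was of NRF2 target genes, 0.4109 over the 41 members on blocks with block medians removed. The same 41 members had 0.407 before removal, so the move came from the members left out. Of 3014 values of the 151 genes taken by the rule for named genes, 2996 kept both, 13 lost the call, 5 gained it and 0 reversed. The losses were of TFRC, MT1X and NFE2L2 and the gains of FTH1, GCLM and ACSL4.

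With the replicate number as a block, 11558 genes changed and 6546 changed at least 2-fold. Same-numbered libraries did not deviate together (r = -0.18, -0.09 and -0.17 across genes), and 0 of 6 libraries correlated best with its own number, so the numbers do not pair the samples. At this depth a gene with 0 counts in a group can be given only a bound. One with 1 to 3 counts can be given a ratio with a wide interval. Changes of 0.5 log2 were recovered in 35.4% of simulated cases. Few genes were changed in that simulation, so the share need not hold for these data.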

Other observations

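The annotation terms, the tests of library totals and of a swap of libraries, and both tests of FTH1 were chosen after the result was seen, and genes named with the terms after their values were seen. Of 1110 terms from the deposited annotation tested with the preset correlation, 60 passed. With an estimated correlation, a test of little power with 6 libraries, 0 passed, and the camera adjusted p of each term below was 0.74. Genes of the term neutrophil chemotaxis were higher in 19 of 24 and lower in 3 (median 2.11, camera adjusted p = 0.00486). CXCL8, a neutrophil chemokine, rose from 215 ± 10.5 to 986 ± 47.9 CPM and the acute phase gene SAA1 from 15.03 ± 2.19 to 265 ± 52.0 CPM (SD, n = 3 each). The term complement activation, classical pathway had 14 of 19 genes higher and 3 lower (camera adjusted p = 0.0405), with C3 going from 287 ± 11.4 to 1713 ± 80.3 CPM while CD55, an inhibitor of complement, fell from 25.7 ± 2.36 to 0.157 ± 0.027 CPM. The semaphorin-plexin signaling pathway had 21 of 30 genes higher and 4 lower (median 1.41, camera adjusted p = 0.00637), SEMA5A among them, from 3.24 ± 0.276 to 60.4 ± 10.7 CPM. The wider cholesterol metabolic process had 32 of 40 genes higher and 3 lower (median 0.78, camera adjusted p = 0.00328), where the narrower biosynthesis list did not pass. Genes of tRNA aminoacylation for protein translation fell in 20 of 26 and rose in 3 (median -0.77, camera adjusted p = 0.0211).

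The genes near 0 in one group were unevenly divided. With at least 5 CPM in one group and at most 3 counts over the other, 137 genes were higher in control and 3 in knockout. Of 2952 annotation terms, 1 was enriched among the 106 protein-coding genes of these higher in control, the homeobox domain (6 of 106 against 34 of the 10707 protein-coding genes with that minimum in control, Fisher's exact test, adjusted p = 0.00259). The 6 include the near-identical copies RHOXF2 and RHOXF2B, and with these counted once, a test chosen after the result was seen, 5 of 105 had the domain (adjusted p = 0.0464).

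Among explanations for most genes differing between the groups, thinning to the smallest total (12128 genes changed) decided nothing about depth, since the totals differed little, but a difference in totals was argued against because the same-group pair with totals farthest apart had an r 0.166 above that of the between-group pair with the closest totals. Base composition was argued against as the whole cause by 6509 genes changed at least 2-fold with GC and length trends removed, and a swap of single libraries by a lowest within-group r that exceeded the highest between-group r by 0.1594. The tests of totals and of a swap rest on the same correlations, so they are not separate support. No dependence on position was predicted for a response to DPP9 loss alone in otherwise like cells. Dependence was predicted for cells that differ in origin or chromosome copy number. The SD of block medians was 2.436 times the highest of 1000 shuffles. Medians of blocks 2 steps apart correlated at 0.3812, where the highest of the shuffles was 0.333. Shuffles also break up neighbouring genes that are regulated together, so the dependence on position cannot by itself decide between these. A candidate explanation is that the groups differ in the origin of their cells as well as in DPP9. The design confounds these, so no change can be assigned to DPP9 alone. 786-O is described as lacking CDKN2A, which had 3385 counts in control and 40 in knockout. On that description the control libraries are those at odds with their label. MTAP (2719 and 6 counts) and CDKN2B (1037 and 1) differed alike. A deleted gene is not regained by cloning, so on that description these values argue against clonal history alone. Only 1 of the 10 splits of the 6 libraries, the real one, gave as many changed genes (12168, highest other 0), as many 2-fold changes (6545, highest other 0) or as many lists (18, highest other 15), and 10 splits are too few for a share under 0.05. Every other split mixes both groups on each side, which widens the spread, so 0 changed genes there decides nothing. Those splits still gave 10 to 15 lists, so the count of lists past the threshold says little about the labels.

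The second pattern is that NRF2 target genes were higher on balance in knockout while SLC7A11, HMOX1, TXNRD1, GCLC and NQO1 were lower. Chromosome position was argued against, since the median of the 41 members on blocks was 0.407 before and 0.4109 after each block median was removed. Scaling moves all genes nearly alike, so the list median less that of all genes (0.6214 with TMM, at lowest 0.6213 with other scalings) decided nothing about it, and the list median itself fell from 0.5928 to 0.2848 with library size alone. The median of all 43 members lay at percentile 99.45 of 10000 random lists matched on expression, and the lower median of the 41 was not placed. That percentile argues against a shift that any random list of like expression would show. Percentiles of other lists did not always match their camera calls with the preset correlation. Glutathione metabolism (99.95) and cytosolic ribosomal proteins (0.11) did not pass, while mitochondrially encoded genes (84.51) and mitosis (3.54) did. Random lists ignore correlation between members. With it estimated (0.0707) the NRF2 target list did not pass (camera adjusted p = 0.363), in a test that 0 of the 40 lists passed. What stays open is how much of the rise depends on scaling and whether the cells differed before DPP9 was lost, so it may not be a response to the knockout.

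The third pattern is the spread of FTH1 within groups, a 10.7-fold range in control and a 4.99-fold range in knockout. Of 6465 genes with at least 20 CPM in each library, FTH1 was the only one more than 2-fold from its group mean in any library. Counting of its reads under the 13 FTH1 pseudogenes listed was argued against, since their excess in the lowest library was at most 0.3556% of the missing FTH1 counts. Joint variation of both ferritin subunits was argued against by FTL, whose range on the log2 scale was 6.17% of that of FTH1 in control and 18.23% in knockout. Loss of reads that map to several places could still differ between libraries and was not tested, nor was another biological explanation, so FTH1 levels here may not measure its expression.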
